A study of Mus musculus with 4 samples.

How the data were processed

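RNA was measured in mouse blastocysts collected on day 4 (96 hours) on 4 Affymetrix arrays. Per the labels, each array received RNA from 1 pool of 30 embryos, extracted with a column kit for small samples, amplified in a pair of rounds and labelled with biotin. The 4 conditions were parthenogenetic diploid, parthenogenetic tetraploid, fertilized diploid and fertilized tetraploid, with 1 array each. Tetraploid embryos had been made by fusion, and the series treats them as stand-ins for a repeat of the diploid embryos of the same origin. No condition has a replicate of its own.

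The authors deposited 1 intensity value per probe set and array, the MAS5 signal on a linear scale. MAS5 (the Affymetrix algorithm that reduces the probe pairs of a probe set to 1 signal) is named in the submitters' processing notes, with no version. Any further step by the authors is not given in the sources used here. The mean signal of each array, with 2% of probe sets trimmed at each end, was 500.0 on all 4 arrays, so the values were used with their deposited scaling. The probe-level files, detection calls and scan dates were not used here, and no batch could be tested.

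The table holds 45101 probe sets, of which 64 are array controls. Gene symbols came from the platform annotation: 34958 probe sets had 1 symbol, 932 had several and 9211 had none. Of those with 1 symbol, 34754 matched the RefSeq gene table of assembly GRCm38.p6 by gene number and 204 did not. No gene was named from a probe set with several symbols. The assembly behind the probes is not given in the sources used here, so no coordinates are printed, and the gene table was used only for names, chromosomes and the order of neighbouring genes.

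Signals were analysed as log2(signal + 10), where 10 is the 10th percentile of all signals rounded to a whole number. A fold change on this scale understates the change of dim genes. Probe sets were kept when their signal reached the median of the array on at least 2 of the 4 arrays, which left 23746 probe sets (52.7% of those that are not controls). Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment over the probe sets kept and a threshold of 0.05. The fit of origin set 2 parthenogenetic against 2 fertilized arrays without a ploidy term and had 2 residual degrees of freedom. The fit of ploidy set 2 tetraploid against 2 diploid arrays with origin as a covariate and had 1. Because both ploidies of an origin serve as its replicates, the p-values measure only the spread between these arrays, which holds ploidy, the pool and technical error together. A comparison inside 1 ploidy rests on 1 array a side and has no test. For such pairs the text gives counts of probe sets that differed at least 2-fold the same way in both pairs, and the correlation of the log2 differences across probe sets, which are not independent replicates.

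The control floor of an array, chosen after seeing the data, is the 95th percentile of the signals of 27 probe sets for bacterial transcripts that the labels do not describe as spiked in. It was 113, 150.3, 145 and 99.7 on the parthenogenetic diploid, parthenogenetic tetraploid, fertilized diploid and fertilized tetraploid array. Where a probe set lay at or below the floor on both arrays of a group, the fold is given as "at least N-fold", with the floor in place of the lower signals. This bound holds for signals only, since a signal above the floor need not come from the named transcript. The number of arrays limits the precision of all values.

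The lists hold imprinted genes (paternally and maternally expressed), Y-linked genes, the X-inactivation centre, blastocyst cell types (trophectoderm, epiblast, primitive endoderm), blastocoel formation, other RNA sources (oocyte, 2-cell stage, cumulus, sperm, fibroblast), p53 targets, apoptosis, mitosis, DNA replication, glycolysis, oxidative phosphorylation, cholesterol synthesis, heat shock, the integrated stress response, epigenetic modifiers, ribosomal proteins, immediate early genes and histones. These 26 lists were written before the data were examined. Genes on the X chromosome form a further list, which had been made conditional on a table of chromosomes. All 27 lists were tested with limma's camera at a preset correlation of 0.01 between genes, on the probe set with the highest mean signal for each of 11404 genes, with adjustment over the lists. Camera with an estimated correlation and limma's fry were alternatives. With an estimated correlation, camera rests on the residual degrees of freedom (2 for origin, 1 for ploidy). A list can then miss the threshold without a high correlation between its genes. For the median of a list in 1 ploidy, the percentile among 10000 random lists of the same size and mean signal is given as a description (1000 for the X chromosome).

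Genes were named by a rule fixed before the data were examined. For origin, it takes the 10 called genes with the highest and the 10 with the lowest log2 difference, with 1 symbol and the same sign in both ploidies. For ploidy it takes 5 each way, filled up with values that did not pass, and for opposite differences in the 2 ploidies 3 each way. Members of the imprinted and Y-linked lists, and up to 4 genes with the smallest p from each other list, could also be named, as could the array controls. Tfrc, Pgap1, Mbnl3, Dynlt3 and 0610012G03Rik, which complete the 29 called genes, were named after their values had been seen.

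The fits were tested on simulated arrays of 23746 probe sets with the spread of the real ones. The simulated noise was independent between probe sets, without correlation between genes or array-wide shifts. This is a more favourable setting than the real arrays. For origin, 2%, 26%, 60% and 88% of 50 probe sets changed by a log2 difference of 1, 2, 3 and 5 were recovered, and 7 unchanged probe sets were called. For ploidy, the shares were 4%, 50%, 58% and 86%, with 28 unchanged probe sets called. A list of 30 probe sets left unchanged had a camera p of 0.53 for origin and 0.037 for ploidy. In 20 simulations without any change, the fit of 2 against 2 arrays without a block called a median of 0 and at most 2 probe sets, the fit with a block a median of 1.5 and at most 12, and the fit of 1 against 2 arrays a median of 4.5 and at most 47. Alternatives tried were pseudocounts of 1 and 34, no filter and a filter at the 75th percentile, quantile normalization and scaling to a common median, ploidy as a block (or origin left out, for ploidy), no intensity trend, all probe sets of a gene averaged, and each array left out in turn. A filter at the control floor was added after seeing the data.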

Results

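The 4 arrays compared blastocysts that developed from activated oocytes without sperm (parthenogenetic, with maternal chromosomes only) with blastocysts from fertilized oocytes, each as diploid embryos and as tetraploid embryos made by fusion. The median signal was 139 on the parthenogenetic diploid, 154 on the parthenogenetic tetraploid, 131 on the fertilized diploid and 104 on the fertilized tetraploid array. Between 47.1% and 55.4% of probe sets lay above the control floor of their array. The pair of fertilized arrays was the most alike, with a correlation of log2 signals across probe sets of 0.90. The parthenogenetic tetraploid array stood apart, with correlations of 0.84 to 0.86 with the other 3, which correlated with each other at 0.87 to 0.90. On that array the ratio of the 3' to the middle probe set of the Actb control, which rises when transcripts are shortened, was 9.28, against 5.13 to 7.55 on the others, and that of Gapdh was 5.22, against 3.72 to 4.08. Its ratios of the 3' to the 5' probe set lay inside the range of the other arrays, at 127 for Actb (108 to 137 on the others) and 24.3 for Gapdh (18.98 to 27.3).

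The series asks how gene expression of parthenogenetic blastocysts differs from that of fertilized ones. Several imprinted genes expressed from the paternal allele were near or below the control floor in parthenogenetic blastocysts and bright in fertilized ones. Sfmbt2, which encodes a Polycomb group protein, had signals of 7.07 (diploid) and 17.4 (tetraploid) in parthenogenetic and 3449 and 4946 in fertilized embryos, at least 29.5-fold lower (log2 difference -7.58 ± 0.46 SE, n = 2 arrays per origin, limma adjusted p 4.04e-05). Phlda2, a placental growth regulator expressed from the maternal allele, was higher by a fitted 38.1-fold, at 2225 and 14678 against 118, below the floor of its array, and 167 (5.25 ± 0.65, adjusted p 0.0054). Genes on the X chromosome were higher as a group (median log2 difference 0.75, camera adjusted p 3.64e-34, adjusted p = 0.22 with an estimated correlation), and Xist, the noncoding RNA that coats an inactive X chromosome, was lower.

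In all, 41 of 23746 probe sets passed the adjusted threshold, 16 higher and 25 lower in parthenogenetic embryos, and all 41 had the same sign in both ploidies. The fit takes the ploidies of an origin as replicates and so favours probe sets that differ the same way in both. The shared sign is therefore no separate evidence of agreement. Of the 41, 33 have 1 symbol and name 29 genes. The rest, with several symbols or none, had differences from -6.68 to 1.87 and enter no gene list. The gene counts below may therefore leave out genes that those probe sets measure. With ploidy as a block, 142 probe sets passed (89 higher and 53 lower), the 41 among them, and without the intensity trend 0 did, while 2103 passed at an unadjusted p under 0.05. Without the parthenogenetic diploid array the count was 715, and without the parthenogenetic tetraploid array 175. Scaling to a common median gave 7 higher and 30 lower, with the median of all probe sets at -0.30 in place of 0.01, and quantile normalization gave 7 higher and 21 lower, with that median at -0.04.

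Of 35 imprinted genes listed as paternally expressed, 30 were on the array and 23 were tested, and 18 of these had lower values in parthenogenetic embryos. Past the threshold over all probe sets, 6 fell and 0 rose, and adjusted over the list alone 8 fell and 0 rose. Besides Sfmbt2, the 6 were Slc38a4, an amino acid transporter (at least 30.2-fold lower, log2 difference -6.86 ± 0.70, adjusted p 0.0011), Gab1, an adaptor of growth factor receptors (at least 24.4-fold lower, -5.84 ± 0.40), the zinc finger genes Plagl1 (a fitted 22.7-fold lower with 1 of its parthenogenetic signals below the floor, -4.51 ± 0.39) and Peg3 (at least 11.6-fold lower, -4.31 ± 0.44), and Jade1, part of a histone acetylation complex (7.54-fold lower, -2.91 ± 0.34). Dimmer tested probe sets of Slc38a4 (-6.04, adjusted p 2.95e-04) and Gab1 (-5.76, 0.0092) passed as well. Those of the other genes did not pass, with differences of -1.88 (adjusted p 0.50) for Sfmbt2, -1.47 (0.75) for Plagl1, -4.18 (0.13) for Peg3, and -4.10 (0.43), -3.39 (0.50) and 0.03 (0.99) for Jade1. Kcnq1ot1, a noncoding RNA (at least 5.40-fold lower, -3.23 ± 0.57, adjusted p 0.065), and Zdbf2 (at least 2.47-fold lower, -2.33 ± 0.80, adjusted p 0.45) passed in the list alone. Other members did not pass: Igf2 differed by -0.35 (adjusted p 0.81), Impact by 0.31 (0.76), and the probe set that stands for Rasgrf1, below the floor on both fertilized arrays, had a fitted difference of 3.07 (0.57, at least 1.80-fold). Its other tested probe set had one of -1.40 (0.75). The median of the list was -0.74 (-0.63 with its 10 members at the floor set to their bounds), camera adjusted p 4.28e-11 and adjusted p = 0.22 with an estimated correlation. The median was -1.37 between the diploid arrays, below all matched random lists, and -0.16 between the tetraploid arrays, at percentile 6.9, a difference between the ploidies that was not tested. It was -0.36 without the parthenogenetic diploid array, -0.45 without the fertilized diploid array, -0.49 without the filter and -3.77 with the filter at the 75th percentile.

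Imprinted genes expressed from the maternal allele lay on the other side. Of 36 listed, 32 were on the array, 23 were tested and 19 had higher values in parthenogenetic embryos. Phlda2 and Grb10, an inhibitor of insulin and growth factor signalling (4.50-fold higher, 2.17 ± 0.31, adjusted p 0.016), rose past the threshold over all probe sets (dimmer probe sets of Grb10 differed by 0.72, adjusted p 0.70, and -0.15, 0.96), and 8 genes rose adjusted over the list alone. The latter include the cell cycle inhibitor Cdkn1c, with signals of 439 and 4374 in parthenogenetic against 159 and 93.6, the latter below the floor, in fertilized embryos (3.41 ± 0.79, adjusted p 0.19 over all probe sets), the noncoding RNA Meg3 (1.02 ± 0.30, 0.35) and Gnas (1.12 ± 0.32, 0.33). Dimmer tested probe sets of Meg3 did not pass either, with -1.10 and -0.63 for those that were lower and 0.37 to 1.35 for the rest. Igf2r differed by 0.38 (0.70) and Ube3a by 0.11 (0.94). The median of the list was 0.89 (0.67 with its 5 members at the floor set to their bounds), 0.74 between diploid and 1.09 between tetraploid arrays, both above all matched random lists. Camera gave an adjusted p of 1.44e-07, an adjusted p = 0.22 with an estimated correlation, and fry 0.021. With common median scaling the median was 0.60, beside -0.30 for all probe sets.

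The Y chromosome cannot be inherited without sperm. Eif2s3y, a Y-linked translation factor gene, had signals of 1.43 and 3.66 in parthenogenetic and 1608 and 2437 in fertilized embryos, at least 14.2-fold lower (-7.32 ± 0.67, adjusted p 5.10e-04). Of the 4 Y-linked genes tested, Eif2s3y fell past the threshold over all probe sets and 3 fell adjusted over the list alone. The others of these 3 were the demethylase gene Kdm5d (at least 2.37-fold lower, -2.41 ± 0.73) and Uty (-1.33 ± 0.45). Dimmer tested probe sets of Uty did not pass, with -1.32 (limma adjusted p 0.69) and -3.41 (0.63). The tested probe set of Uba1y, below the floor on both fertilized arrays, had a fitted difference of 2.27 (adjusted p 0.65, at least 1.38-fold), and another, below the filter, had signals of 109 and 140.05 against 103 and 138. Parthenogenetic embryos lack a Y chromosome, so the signals of 183 and 158 from the tested probe set cannot be ascribed to Uba1y. The median was -1.87 (-1.29 with 3 members at their bounds), with a camera adjusted p of 8.86e-04 and adjusted p = 0.59 with an estimated correlation. Without the fertilized tetraploid array the adjusted p was 0.167.

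**Figure D1:**
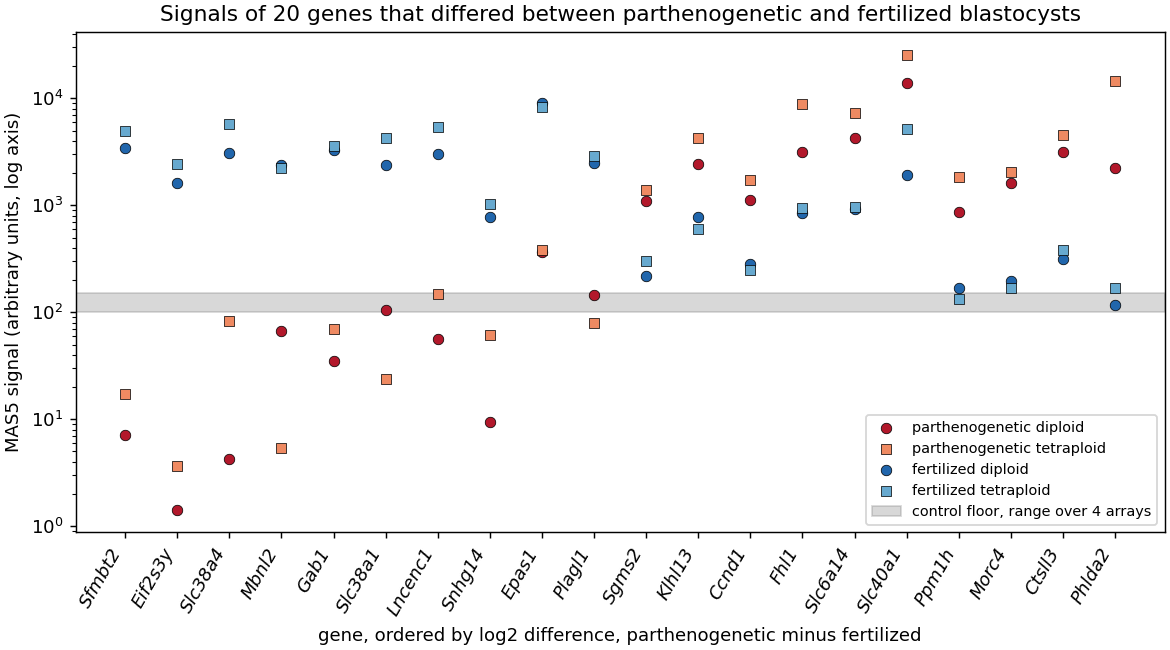
MAS5 signals (vertical log axis, arbitrary units) of the 20 genes named by rule for the comparison of origin, ordered from the lowest to the highest log2 difference; each point is 1 array, red or orange for parthenogenetic and blue for fertilized, circles for diploid and squares for tetraploid, and the grey band is the range of the control floor over the 4 arrays (99.7 to 150.3). For the 10 genes on the left, parthenogenetic signals are at most 383 (Epas1) and fertilized ones at least 786 (Snhg14); for the 10 on the right, both parthenogenetic signals lie above both fertilized ones.

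Of 391 genes tested on the X chromosome, 360 (92.1%) had higher values in parthenogenetic embryos, and 77.5% were higher in both ploidies. Their median log2 difference was 0.75, 0.68 between the diploid and 0.85 between the tetraploid arrays, while the medians of the 19 autosomes lay between -0.08 and 0.05. Past the threshold over all probe sets, 6 rose and 0 of the probe sets that stand for a gene fell, and adjusted over the list alone 84 rose and 1 fell. The 6 were Morc4, a chromatin protein gene (9.58-fold, 3.26 ± 0.35, adjusted p 0.0017), the amino acid transporter Slc6a14 (5.86-fold, 2.55 ± 0.32), the LIM protein Fhl1 (5.84-fold, 2.55 ± 0.42), Klhl13, which takes part in mitotic ubiquitination (4.71-fold, 2.23 ± 0.35), the splicing regulator Mbnl3 (2.83-fold, 1.503 ± 0.25) and the dynein light chain Dynlt3 (2.67-fold, 1.41 ± 0.24). Camera gave an adjusted p of 3.64e-34, an adjusted p = 0.22 with an estimated correlation, and fry 0.065. With common median scaling the median was 0.43, beside -0.30 for all probe sets.

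Xist fell in parthenogenetic embryos by 2 of its 3 tested probe sets. One gave signals of 1138 and 841 against 9386 and 12514 in fertilized embryos (10.97-fold lower, -3.46 ± 0.29, adjusted p 2.95e-04) and another a difference of -2.80 ± 0.36 (adjusted p 0.0062). The third and brightest, which stands for the gene in the lists, differed by -1.34 ± 0.23 (adjusted p 0.059). Among the 5 genes tested from the X-inactivation centre and its regulators, 0 passed over all probe sets. Adjusted over the list alone, Xist fell and the ubiquitin ligase gene Rlim rose (0.83 ± 0.29, beside a median of 0.75 for all X-linked genes tested). The median of this list was -0.09 (camera adjusted p 0.58).

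**Figure D2:**
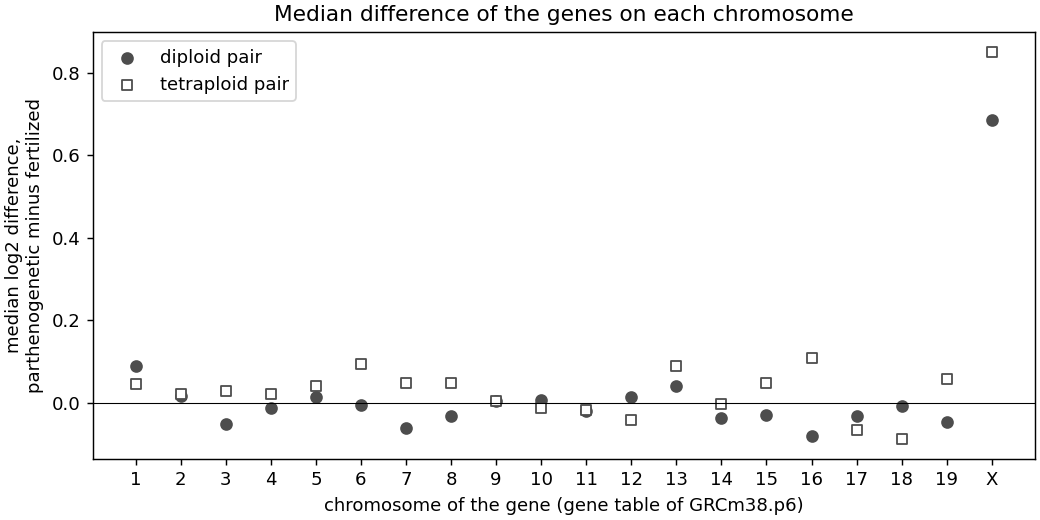
Median log2 difference, parthenogenetic minus fertilized (vertical axis), of the genes on each chromosome (horizontal axis), as filled circles for the diploid and open squares for the tetraploid pair of arrays. The X chromosome lies at 0.68 and 0.85, and every autosome between -0.09 and 0.11.

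Outside the listed imprinted, Y-linked and X-linked genes, 6 genes fell. Mbnl2, a regulator of splicing, was at least 16.5-fold lower by one probe set (-6.07 ± 0.65, adjusted p 0.0016) and a fitted 7.37-fold lower by another (-2.88 ± 0.41, 0.015). Its other 3 probe sets differed by -0.74 to 1.34 and did not pass. Also lower were the amino acid transporter Slc38a1, at least 22.9-fold (-5.69 ± 0.55; a further probe set differed by -1.36, adjusted p 0.30), the long noncoding RNA Lncenc1, at least 28.6-fold (-5.30 ± 0.46), and Snhg14, at least 6.48-fold (-4.61 ± 0.70). Snhg14 hosts small nucleolar RNAs and is known to be expressed from the paternal allele, although it was not on the list. Epas1, a hypoxia-inducible transcription factor, was bright enough to be measured on all 4 arrays, at 365 and 383 against 9153 and 8337 (22.8-fold lower, -4.51 ± 0.29, adjusted p 4.04e-05). The gene 0610012G03Rik was 4.76-fold lower (-2.25 ± 0.36). Genes that rose were the cathepsin Ctsll3 (10.7-fold, 3.41 ± 0.33, adjusted p 6.95e-04), the phosphatase Ppm1h (7.93-fold, 2.99 ± 0.43), the iron exporter Slc40a1 (5.98-fold, 2.58 ± 0.42), cyclin D1, which drives entry into S phase (Ccnd1, 5.09-fold, 2.35 ± 0.36) and the sphingomyelin synthase Sgms2 (4.63-fold, 2.21 ± 0.37). The transferrin receptor Tfrc (3.66-fold, 1.87 ± 0.26) and Pgap1, which remodels GPI anchors (3.46-fold, 1.79 ± 0.28), rose as well.

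Genes of mitosis, DNA replication, oxidative phosphorylation and the ribosome shifted down as lists at camera's preset correlation, with 0 members past the threshold in any of them over all probe sets. For each of these 4 lists the adjusted p = 0.70 with an estimated correlation. Of 31 mitosis genes, 28 had lower values in parthenogenetic embryos (median -0.41, camera adjusted p 4.06e-05, adjusted p = 0.70 with an estimated correlation), for example Ccnb2 (-0.95 ± 0.30) and Aurka (-0.77 ± 0.33). Of 37 replication genes 30 were lower (median -0.33, 2.69e-04), for example Rfc4 (-1.01 ± 0.34). Of 64 genes of oxidative phosphorylation 51 were lower (median -0.28, 6.72e-05), for example Ndufa4 (-0.93 ± 0.30), and of 42 ribosomal protein genes 32 (median -0.15, 0.016), for example Rpl10a (-0.61 ± 0.25). With common median scaling the 4 medians were -0.73, -0.66, -0.60 and -0.48, beside -0.30 for all probe sets. The mitosis median was -0.10 between the diploid and -0.77 between the tetraploid arrays, the latter pair holding the array with the highest 3' to middle ratios of Actb and Gapdh, though not the highest 3' to 5' ratios. Without that array, the parthenogenetic tetraploid one, the medians of mitosis, replication and ribosomal genes were 0.051 (adjusted p 0.94), -0.18 (0.085) and -0.07 (0.30). Without the parthenogenetic diploid array those of mitosis and replication were -0.81 and -0.53. Ribosomal genes had -0.03 without the fertilized diploid array (0.64) and -0.30 without the fertilized tetraploid array. They did not pass with the filter at the 75th percentile (0.088), without the intensity trend (0.11) or with all probe sets averaged (0.11). Oxidative phosphorylation genes had -0.18 without the fertilized diploid array.

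Markers of the epiblast and of pluripotency had a median of -0.34 (19 of 28 lower, camera adjusted p 0.016, adjusted p = 0.70 with an estimated correlation), with Nanog, a pluripotency transcription factor, at -0.73 ± 0.31. Sall1 (-1.84 ± 0.37, adjusted p 0.12) fell adjusted over the list alone. Genes of the integrated stress response had a median of 0.18 (24 of 30 higher, 0.0086, adjusted p = 0.70 with an estimated correlation), with the aminoacyl-tRNA synthetase gene Gars at 0.89 ± 0.27 and the amino acid transporter Slc7a5 at 1.14 ± 0.38. In both lists 0 members passed over all probe sets. The epiblast median was -0.03 without the parthenogenetic tetraploid array (0.95), -0.27 without the fertilized diploid array (0.17), -0.51 without the parthenogenetic diploid array, -0.18 with all probe sets averaged and -0.66 with common median scaling, and the list missed the threshold without the intensity trend (0.052). The stress response median was 0.73 between the diploid and -0.06 between the tetraploid arrays. It was 0.04 without the parthenogenetic diploid (0.98), 0.57 without the parthenogenetic tetraploid, 0.09 without the fertilized diploid (0.29) and 0.39 without the fertilized tetraploid array. It was -0.14 (0.062) with common median scaling, where all probe sets had -0.30, and not past the threshold without the trend (0.069).

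**Figure D3:**
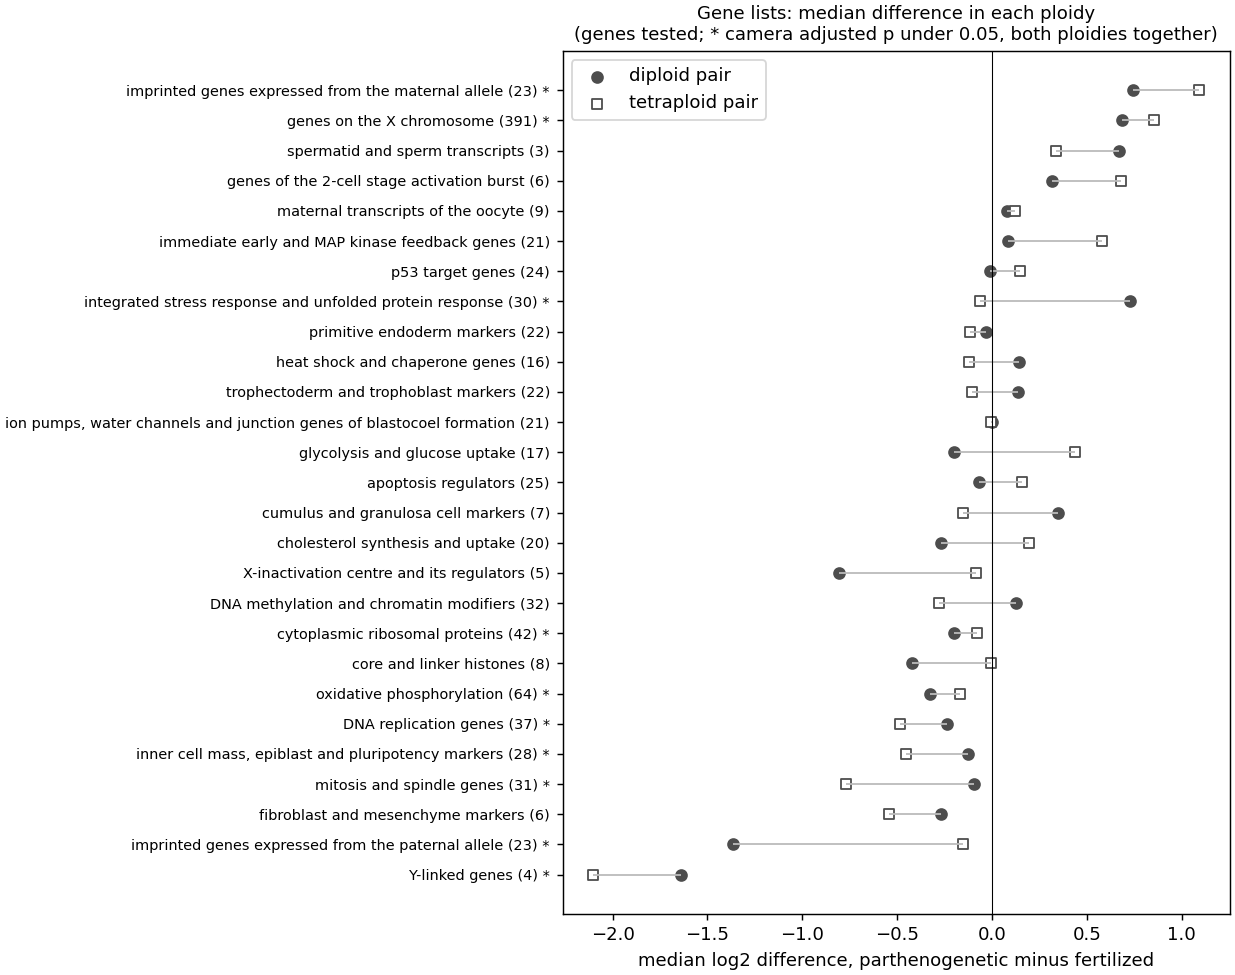
Median log2 difference, parthenogenetic minus fertilized (horizontal axis), of the genes of each of the 27 lists (rows, with the number of genes tested), as filled circles for the diploid and open squares for the tetraploid pair of arrays, joined by a grey line; stars mark a camera adjusted p under 0.05 at the preset correlation. The medians of the 2 pairs lie at 0.74 and 1.09 for maternally expressed imprinted genes, at -1.37 and -0.16 for paternally expressed ones, and at -0.10 and -0.77 for mitosis genes.

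Markers of the other cell lineages and of possible other RNA sources did not pass camera. Trophectoderm markers had a median of 0.14 with a mean of -0.06 (22 tested), and the trophoblast gene Plac1 differed by 1.40 ± 0.25 (adjusted p 0.071), past the threshold adjusted over the list alone. Primitive endoderm markers had a median of 0.18 (22 tested; camera's direction was down), blastocoel genes 0.13, oocyte transcripts 0.41 (9 tested), 2-cell stage genes 0.50 (6), cumulus markers 0.01 (7), sperm transcripts 0.50 (3) and fibroblast markers -0.58 (6). The remaining lists were p53 targets with a median of 0.24, apoptosis 0.06, glycolysis 0.13, cholesterol synthesis -0.06, heat shock 0.17, epigenetic modifiers -0.11 (mean 0.03), immediate early genes 0.29 and histones -0.26. Over these 16 lists the adjusted p lay between 0.23 and 0.94, and 0 members passed over all probe sets. Adjusted over their list alone, Plk2 (1.91 ± 0.44) and Zmat3 (1.32 ± 0.34) rose among p53 targets, Dusp1 (1.53 ± 0.38) and Atf3 (at least 2.87-fold, 3.51, adjusted p 0.34 over all probe sets) rose and Dusp4 (-2.03 ± 0.50) fell among immediate early genes, and Hook1 (1.18 ± 0.30, sperm) rose, while Stip1 (-1.35 ± 0.36, heat shock) and H2az2 (-1.44 ± 0.42, histones) fell.

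Agreement between the ploidies was partial across all probe sets. A 2-fold difference the same way in both ploidies was seen for 1356 probe sets (880 higher and 476 lower in parthenogenetic embryos), and a 2-fold difference in opposite directions for 883. Quantile normalization gave 633 higher and 594 lower, and common median scaling 478 and 817. The correlation of the diploid with the tetraploid log2 differences was 0.14 (Spearman's rho 0.17) across 23746 probe sets, and 0.41 across probe sets at or above the 75th percentile.

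Between tetraploid and diploid blastocysts, the comparison shows how far the stand-in replicates differ. Primitive endoderm markers were lower in tetraploid embryos as a list: 20 of 22 had lower values (median -0.69, camera adjusted p 1.15e-13, adjusted p = 0.93 with an estimated correlation), and adjusted over the list alone 9 fell, among them the endocytic receptors Cubn (-1.67 ± 0.29) and Lrp2 (-0.90 ± 0.26) and the basement membrane genes Col4a1 (-1.09 ± 0.25) and Lama1 (-1.12 ± 0.27). Genes of cholesterol synthesis were higher as a list: 18 of 20 had higher values (median 0.55, or 0.28 with all probe sets averaged, camera adjusted p 3.41e-10, adjusted p = 0.93 with an estimated correlation), and adjusted over the list alone 6 rose, among them Cyp51 (1.40 ± 0.27, signals of 4000 and 2790 against 1638 and 968), Insig1 (0.85 ± 0.26), Sqle (0.79 ± 0.25) and Lss (0.94 ± 0.31). Both shifts were present in each origin, with medians of -0.81 (parthenogenetic) and -0.61 (fertilized) for primitive endoderm and 0.55 and 0.35 for cholesterol synthesis. For both lists fry gave 0.58.

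A further 5 lists passed camera at the preset correlation. With an estimated correlation the adjusted p = 0.94 for mitosis and adjusted p = 0.93 for each of the other 4. Mitosis genes had a median of -0.45 (28 of 31 lower, adjusted p 1.24e-09), with -0.77 between the parthenogenetic and -0.12 between the fertilized arrays, and Prc1 and Cdk1 differed by -1.18 ± 0.28 and -1.39 ± 0.35. Epiblast markers had -0.38 (26 of 28 lower, 6.15e-05), with -0.59 between the parthenogenetic and -0.15 between the fertilized arrays and Sox2 at -0.79 ± 0.33. For both lists the larger shift lay in the pair with the parthenogenetic tetraploid array, which had the highest 3' to middle ratios of Actb and Gapdh. Ribosomal proteins had -0.24 (35 of 42 lower, 8.06e-04). Replication genes had -0.19 (27 of 37 lower, 0.024) and p53 targets 0.18 (18 of 24 higher, 0.014). The p53 and replication lists no longer passed with origin left out of the model (0.053 and 0.059), with common median scaling (0.052 and 0.24) or without the intensity trend (0.13 and 0.23), and ribosomal proteins not in the last (0.066). With common median scaling the medians of replication and ribosomal genes were -0.11 and -0.16. The p53 list also missed the threshold with all probe sets averaged (0.15).

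Imprinted genes did not shift with ploidy as lists, with medians of 0.23 (paternally expressed) and -0.07 (maternally expressed), nor did X-linked genes (-0.01) or Y-linked genes (0.25). Adjusted p for the 20 lists that did not pass lay between 0.071 and 0.98. The others among them were the X-inactivation centre (-0.07), trophectoderm (0.04), blastocoel (-0.03), oocyte (-0.25), 2-cell stage (-0.25), cumulus (0.10), sperm (0.12), fibroblast (-0.80), apoptosis (0.19), glycolysis (-0.04), oxidative phosphorylation (-0.15), heat shock (-0.07), stress response (-0.25), epigenetic modifiers (-0.11), immediate early genes (0.17) and histones (-0.08). The median and camera's direction differed in sign for maternally expressed imprinted genes, the X-inactivation centre, blastocoel genes, histones and X-linked genes.

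By limma, 0 of 23746 probe sets passed between tetraploid and diploid arrays (smallest adjusted p 0.19), and 1424 passed at an unadjusted p under 0.05. With quantile normalization 53 passed, without the filter 73, with a pseudocount of 1 19, with common median scaling 11 and with the filter at the control floor 2. The 10 genes named by rule did not pass and were at or below the floor on both arrays of one ploidy. Banf2, Col8a1, 2310065F04Rik, Arhgef12 and a dim probe set of Eif2s3y were at least 1.29-fold to 1.61-fold higher in tetraploid embryos, and Hoxb5os, Smtn, Sys1, Vipas39 and Rcn3 at least 1.41-fold to 3.24-fold lower (Smtn, log2 difference -4.22 ± 1.20, adjusted p 0.66). The signal of 166 from this Eif2s3y probe set on the parthenogenetic tetraploid array cannot be ascribed to the Y-linked gene, which those embryos lack. A 2-fold difference the same way in both origins was seen for 860 probe sets (365 higher and 495 lower in tetraploid embryos) and in opposite directions for 835. Quantile normalization gave 412 higher and 392 lower, and common median scaling 417 and 377. The correlation of the parthenogenetic with the fertilized log2 differences was 0.0028 (Spearman's rho 0.035).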

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

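The tests of explanations in this part were chosen only after the results they bear on had been seen. The fitted difference between origins went opposite ways in the 2 ploidies for 6 genes picked by the naming rule, and these differences between ploidies were not tested. Between the diploid arrays, parthenogenetic minus fertilized, the log2 differences were 3.25 for Inpp1, 3.47 for Arvcf, 3.41 for Emsy, -3.96 for Ccdc141, -4.00 for Slc41a3 and -3.46 for Saxo2, and between the tetraploid arrays they were -3.38, -3.25, -3.23, 3.78, 3.71 and 3.59. In every pair the lower signal was below the control floor of its array, so these sizes depend on the pseudocount: the diploid pairs support at least 1.48-fold (Emsy) to at least 2.32-fold (Slc41a3), the tetraploid pairs at least 1.34-fold (Inpp1) to at least 2.14-fold (Saxo2), and the tetraploid pair of Emsy supports no direction. The middle control probe set for 18S ribosomal RNA, which no comparison uses, had a signal of 3249 on the fertilized diploid array and 756 to 1024 on the other 3.

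Genes on the X chromosome were higher in parthenogenetic embryos. Scaling between arrays is argued against by the autosomes: the X median exceeded that of the highest autosome by at least 0.67 under the deposited scaling, quantile normalization and common median scaling. Dim signals are argued against as well, since the X-linked genes in the top 25 percent of mean signal had a median of 0.69. A candidate explanation is that parthenogenetic embryos had 2 active X chromosomes where fertilized embryos, male or with an inactivated X chromosome, had 1: 92.1% of X-linked genes were higher, with medians under 1 in both ploidies, and Xist was lower. For the X-linked genes as a set, the sex mix of the fertilized pools alone, with no inactivation in any embryo, stays open. Equal sexes would give 0.42, below the 0.75 seen, but the sex ratio of the pools is unknown. The sex mix alone leaves Xist unaccounted for if its RNA follows the number of X chromosomes, which was not tested. Fewer X chromosomes in the fertilized pools would then make Xist higher in parthenogenetic embryos, yet its called probe sets were lower (-3.46 and -2.80). Its brightest probe set was lower as well, without passing.

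Of the genes outside the fixed lists, 6 fell strongly in parthenogenetic embryos. A near-complete loss of the trophectoderm, epiblast or primitive endoderm is argued against. The lowest lower quartile among their markers was -0.67, far above the smallest of these falls, -2.25. The lowest single epiblast marker lay at -2.26. Loss of a part of a lineage, or of cells that these lists do not mark, was not tested. Of the 6, Snhg14 is itself known as paternally expressed, and whether Slc38a1 fell as a neighbour of a listed imprinted gene (2 protein-coding genes from Slc38a4 in the gene table of GRCm38.p6) stays open: 1 of the 5 without Snhg14 lies within 10 such genes, against 3.01% of the tested genes outside the lists (one-sided Fisher exact test, p 0.14; 2 of 6 and p 0.013 with Snhg14). The other 4, Epas1, Mbnl2, Lncenc1 and 0610012G03Rik, lie farther away or on chromosomes with no listed imprinted gene. That these 4 are themselves expressed from the paternal allele is a hypothesis, which arrays without allele information cannot test.

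Mitosis genes were lower on the parthenogenetic tetraploid array than on the other 3. Noise of dim signals that differs from gene to gene is argued against, since the median difference of the tetraploid pair, -0.77, lay below all of 10000 random lists matched on signal. Noise shared by mitosis genes on the parthenogenetic tetraploid array was not tested, because those lists hold unrelated genes. The estimated correlation between mitosis genes was 0.68 in the fit of origin. The residuals of that fit hold the differences between ploidies, the shift of this array included. The value is therefore no separate evidence of shared noise. Lower RNA or amplification quality on that array cannot be told apart from an effect in the embryos, because there is only 1 such array: its 3' to middle ratios of Actb (9.28) and Gapdh (5.22) were the highest, but its 3' to 5' ratios (127 and 24.3) lay inside the range of the other 3, over which mean mitosis signals were lower with a higher Gapdh 3' to middle ratio but did not follow the Actb one. An effect of ploidy in parthenogenetic embryos, which the design names, stays among the open explanations and was not tested apart from the quality of that array.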

How the results depend on the processing

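The alternatives were chosen before the data were examined, except the filter at the control floor and every setting for the X chromosome, and the count over other splits was chosen afterwards. All 33 called probe sets with 1 symbol kept their direction in every alternative fitted to probe sets, and 23 to 33 of them stayed past the threshold, except that 0 did without the intensity trend. The direction could not change with the block, without the trend or with another filter, since these leave the fitted difference as it was. Fits with an array left out reuse arrays that gave the calls. The 41 calls between origins became 142 with ploidy as a replicate block and 0 without the trend, and 46 to 715 with 1 array left out, where the lone array is assumed to vary like the others; the cause was not tested, although simulations without change gave up to 47 calls in such a fit. Of the 3 ways to split the 4 arrays into pairs, 1 gave as many calls as the real split, which is the real one (41, against 0 for the highest other), and 3 splits are too few for a share under 0.05. The 10 lists called between origins became 0 with an estimated correlation, 1 with fry and 7 to 11 with an array left out. A miss with an estimated correlation does not by itself show that correlation between genes undid a shift, since that test has few degrees of freedom. For maternally expressed imprinted genes the estimated correlation was -0.043, under the preset 0.01. Their unadjusted camera p for origin still rose from 1.61e-08 to 0.025. For mitosis genes the estimated correlation for origin was 0.68, from residuals that hold the differences between ploidies. The medians of the imprinted, Y-linked and X-linked lists do not depend on the list test: -0.74, 0.89, -1.87 and 0.75 all missed the threshold with an estimated correlation (adjusted p 0.22, 0.22, 0.59 and 0.22), and all but 0.89 with fry (0.11, 0.065 and 0.065 for the others). With an array left out they ranged from -1.05 to -0.36, 0.69 to 0.96, -2.09 to -1.65 and 0.63 to 0.80, and the Y-linked list missed the threshold without the fertilized tetraploid array. The mitosis median ranged from -0.81 to 0.051 with an array left out and turned positive without the parthenogenetic tetraploid array, and the stress response median became -0.14 under common median scaling, which by construction lowers all genes (all probe sets to -0.30) and leaves this list above that median. The 0 calls between ploidies became 19 with a pseudocount of 1, 73 without the filter, 53 with quantile normalization, 11 with common median scaling and 2 with the floor filter, and its 7 lists became 4 without the trend and 0 with an estimated correlation or fry. Leaving out the origin term changed neither call of ploidy by over 1.5 times (0 probe sets and 5 lists). Counts of probe sets 2-fold the same way, 1356 for origin and 860 for ploidy, depended on the filter, as number and as share of the probe sets tested: 4465 and 3569 without the filter, 306 and 68 at the 75th percentile. The origin correlation of 0.14 was 0.13 with a pseudocount of 1, 0.17 with 34, 0.061 without the filter, 0.41 at the 75th percentile and 0.16 with the floor filter, and the ploidy correlation of 0.0028 was 0.12 at the 75th percentile. The fit of ploidy with an array left out has no residual degrees of freedom and was not run, and the Y-linked list has too few genes at the 75th percentile. The cause of these changes was not tested. Signal over background limits dim genes, since 47.1% to 55.4% of probe sets lay above the floor.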

Other observations

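The groups and tests in this part were chosen after the data had been seen. Genes that move iron into and out of cells were among the called genes: the exporter Slc40a1 (13888 and 25455 in parthenogenetic against 1913 and 5138 in fertilized embryos) and the transferrin receptor Tfrc (5708 and 5951 against 1597 and 1576). Of 14 iron genes tested from a list written afterwards, these 2 rose and 0 fell, and 11 had higher values (median 0.30). The importer Slc11a2 differed by 1.18 ± 0.42 (limma adjusted p 0.48) and the storage protein gene Fth1 by 0.28 ± 0.29 (0.78).

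Amino acid transporters went both ways. Of 19 tested from another such list, Slc38a1 and Slc38a4 fell and Slc6a14 rose. Another member of the family, Slc38a2, had signals of 1605 and 649 in parthenogenetic against 4237 and 3858 in fertilized embryos (-1.97 ± 0.39, limma adjusted p 0.11). Slc7a5 differed by 1.14 ± 0.38 (0.43), with signals of 3233 and 1524 in parthenogenetic against 863 and 1157 in fertilized embryos. Slc7a3 differed by 1.07 ± 0.46 (0.55), at 4501 and 1417 against 1002 and 1427, so its higher value lay in the diploid pair alone. The median of the list was 0.26. Among 4 placental cathepsin and trophoblast genes tested, Ctsll3 was the called one, and the related Ctsl differed by -0.55 ± 0.30 (0.61).

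The shift of X-linked genes was present at every signal level. All genes tested were divided by mean signal into 4 groups, which held 90, 80, 104 and 117 X-linked genes from the dimmest to the brightest. In these, the median log2 difference was 0.89, 0.79, 0.74 and 0.69 (0.62, 0.63, 0.72 and 0.68 between the diploid, 1.04, 0.90, 0.77 and 0.73 between the tetraploid arrays), and 83.3%, 88.8%, 96.2% and 97.4% of the X-linked genes were higher in parthenogenetic embryos.

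Phlda2 and Cdkn1c, both imprinted and expressed from the maternal allele on chromosome 7, had their highest signals on the parthenogenetic tetraploid array, at 14678 and 4374, against 2225 and 439 on the parthenogenetic diploid array. With 1 array per condition this difference has no test.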
